A study of Mus musculus with 30 samples.

How the data were processed

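RNA sequencing libraries from 30 mouse samples were compared: bone marrow cells of WT and KO animals cultured with GM-CSF, in 10 groups of genotype and time after addition of viable Aspergillus fumigatus conidia (0, 3, 6, 9 and 12 h), with 3 libraries each. The deposited gene table holds whole-number counts per Ensembl gene, with different totals per library, and it was taken as raw counts of the authors from these values. Per the submitters' processing notes, Trimmomatic 0.35, HISAT2, StringTie and DESeq2 and the mouse build GRCm38 were used. Their order, the annotation release, the strand setting and how the counts were taken from StringTie's output are not given in the sources used here. Counts derived from StringTie coverage can be rounded estimates, and reads of near-identical copies, overlapping genes or antisense genes may be split between genes in ways the table does not show. The deposited table of each of 13 comparisons gives log2 fold changes by the authors, per the file headers. Its p-values and adjusted p-values are the authors' as well, per the file headers, with the column names that DESeq2 writes and with only genes under an adjusted p of 0.05 listed. The deposited mean normalized signal per gene in these tables was not used. No column of per-sample values was left out of use (0 columns).

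The table held 54532 genes, of which 46958 had a count in any library. Names, biotypes and coordinates came from GENCODE M21 on GRCm38, in which 54495 of the Ensembl IDs were found and 37 were not. Total counts ran from 1722384 to 3509429 per library with a median of 2492886. At this depth a gene at 5 CPM, the lowest level at which a gene was named by size of change, rests on few reads, so small changes of low genes were not detectable. Where a group had no count, a bound was computed against 3 counts over the group, and ratios of groups with 1 to 3 counts carry an exact interval (95%). Such intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries within a group had counts that agreed within sampling noise.

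Genes were kept with edgeR's filterByExpr (minimum count 10), which left 12393 genes and removed 42139 while keeping 98.66% of the counts. Of the genes kept 10504 were protein-coding, 265 were structural or small RNA genes and 1624 were others. Libraries were scaled by TMM factors, and a negative binomial model with 1 coefficient per group was fitted to all 30 libraries with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood, residual degrees of freedom 20, prior degrees of freedom 6.03). The common dispersion was 0.01863, a biological coefficient of variation of 13.7%. Each later time was tested against 0 h within a genotype, KO against WT at each time, and the mean of the KO groups against the mean of the WT groups. The interaction was an F test of the 4 differences between genotypes in the change from 0 h. P-values are two-sided and adjusted by Benjamini-Hochberg over all genes kept, with a threshold of 0.05. Standard errors are those of the fitted log2 changes, and CPM values are counts divided by the scaled library totals, with a prior count of 2 where logs were taken. The main tests, the gene lists, the rule for named genes and the first group of alternatives below were chosen before the data were examined.

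Gene lists covered inflammatory cytokines and chemokines, NF-kappaB feedback and subunit genes, immediate early transcription factors, the type I interferon response, fungal recognition and the inflammasome, mitochondrial antiviral genes with Nlrx1 partners, glycolysis, hypoxia, nuclear-encoded and mitochondrially encoded oxidative phosphorylation, and cholesterol synthesis. Others covered NRF2 targets, NADPH oxidase and lysosomal killing, antigen presentation, dendritic cell maturation, the unfolded protein and integrated stress response, heat shock, iron and metal handling, the cell cycle and apoptosis. Markers of neutrophils, macrophages, conventional and plasmacytoid dendritic cells, B cells, T and NK cells, mast cells and basophils, eosinophils, erythroid cells and megakaryocytes, stromal cells and sex were included, since cultures of marrow can hold such cells. In all 12 genes stood in more than 1 list. Each list was tested with camera from limma 3.58.1 on log2 CPM (preset correlation 0.01), adjusted over the lists of a family of comparisons, and again with an estimated correlation. 28 lists had enough tested members.

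Named genes followed a fixed rule. Nlrx1 came first in each library. A set of 36 genes could be named anywhere (Nlrx1, Tnf, Il1a, Il1b, Il6, Il10, Il12b, Il23a, Cxcl1, Cxcl2, Cxcl10, Ccl20, Ifnb1, Ifit1, Isg15, Clec7a, Clec4e, Nlrp3, Ptx3, Nos2, Hmox1, Ldha, Hk2, Mavs, Tufm, Traf6, Nnt, Egr1, Egr2, Fos, Sqstm1, Tnfaip3, Nfkbia, H2-Aa, Cd86 and Ccr7), of which Il10, Nos2, Ccl20 and Ifnb1 fell below the filter. Among genes past the threshold with at least 5 CPM in the higher group, no overlap between the libraries of both groups and a symbol other than a predicted or clone name, the 3 largest rises and 3 largest falls were taken at 3, 6 and 9 h, and 8 of each at 12 h. Between genotypes and on average 5 of each were taken (on average with every time's KO mean on the same side), and for the interaction the 8 lowest adjusted p-values. From each list up to 4 members past the threshold with the lowest adjusted p were added. Marker genes, and the 5 kept genes on each side of Nlrx1, could be named. Some genes that this rule takes are not reported here.

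The tests were run on simulated counts with the real means, library sizes and spread, in which 67, 67 and 66 of 12393 genes were changed 1.5-fold, 2-fold and 4-fold. For KO 12 h against 0 h 28.4%, 62.7% and 87.9% of them were recovered, with 4.03% of the calls false. For KO against WT at 12 h the shares were 32.8%, 56.7% and 84.8% (0.85% of the calls false), and for the interaction 11.9%, 34.3% and 59.1%. For the average over times, where the simulated change was in 1 group alone and so was diluted, they were 3.0%, 11.9% and 48.5% (2.33% of the calls false). No gene was called by edgeR in the simulated comparisons without changed genes. A simulated list shifted 1.5-fold for KO against WT at 12 h had a camera adjusted p of 1.16e-55, and no other list passed.

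The first group of alternatives held DESeq2 1.42.0, RLE size factors, no count filter (at least 1 count in any library, 46958 genes), a filter of at least 1 CPM in at least 6 libraries, which keeps 20364 genes and so more than the main filter, the replicate number as a block over all libraries or within genotype, a fit of the 6 libraries of a comparison alone, and each library left out in turn. After the data were seen 5 more were added: protein-coding genes alone, removal of 433 tested genes whose counts switched at least 8-fold within a group (highest count at least 20), the share of small RNA in each library (small nucleolar, small nuclear, Cajal body, micro and miscellaneous RNA biotypes, 235 of them tested, without rRNA and tRNA) as a covariate, list tests of the interaction at each time, and list tests with each library left out in turn. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.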

Results

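RNA was sequenced from mouse dendritic cells grown from bone marrow with GM-CSF, a growth factor that drives myeloid precursors towards dendritic cells. The cells came from wild-type animals (WT) and from animals lacking Nlrx1 (KO), a NOD-like receptor family member found at mitochondria. They were collected before challenge (0 h) and 3, 6, 9 and 12 h after viable spores (conidia) of the mould Aspergillus fumigatus were added, with 3 libraries in each of the 10 groups of genotype and time. Total counts per library ran from 1722384 to 3509429 with a median of 2492886. The design asks how the cells respond to the fungus over time, whether loss of Nlrx1 changes their transcripts, and whether it changes the response itself. The labels do not say whether the 3 libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. Log2 changes are given ± standard error of the fit, expression levels as means of counts over scaled library totals (CPM) ± SD with n = 3 libraries, and p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Counts of list members are given as adjusted over all 12393 genes tested and, in parentheses, over the list alone, with rises before falls. Gene lists were tested as a whole with camera, whose calls held with an estimated correlation between genes unless a second p is given. The call of each gene named here held with any 1 library left out, unless stated.

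Nlrx1 (ENSMUSG00000032109, chromosome 9, 44252717 to 44268599 in GRCm38) was detected in all 15 WT libraries, with counts of 13 to 46 (5.26 to 14 CPM) and a mean of 9.32 ± 2.93 CPM (SD, n = 15). In the libraries labelled KO its counts were 0 to 14 (0 to 5.68 CPM, mean 2.48 ± 1.75 CPM, SD, n = 15). The WT counts were 38, 19 and 24 at 0 h, 22, 16 and 13 at 3 h, 14, 32 and 15 at 6 h, 38, 27 and 46 at 9 h, and 34, 17 and 20 at 12 h. The KO counts in the same order were 2, 7 and 5, then 12, 4 and 3, then 3, 12 and 0, then 11, 8 and 0, and finally 9, 14 and 3. Averaged over the times Nlrx1 was lower in KO, with a log2 change of -1.87 ± 0.28 (adjusted p = 1.71e-05). At single times it was lower at 0 h (-2.36 ± 0.65, adjusted p = 0.0326) and 9 h (-2.33 ± 0.60, adjusted p = 0.0209), and the values at 3, 6 and 12 h were -1.68, -1.83 and -1.15 without passing the test. Neither single call held with each library left out. For Nlrx1 at 0 h the call ended without WT 0 h replicate 1 (adjusted p = 0.114) or 3 (0.061), without KO 0 h replicate 1 (0.129), 2 (0.0672) or 3 (0.0906) and without a count filter (0.0763), and at 9 h without WT 9 h replicate 1 (0.052) or 3 (0.0725), without KO 9 h replicate 2 (0.063) or 3 (0.0829) and in a fit of the 6 libraries alone (0.0978). Which part of the gene was deleted is not given in the sources used here, so residual counts in KO do not show whether an intact transcript remained.

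**Figure D1:**
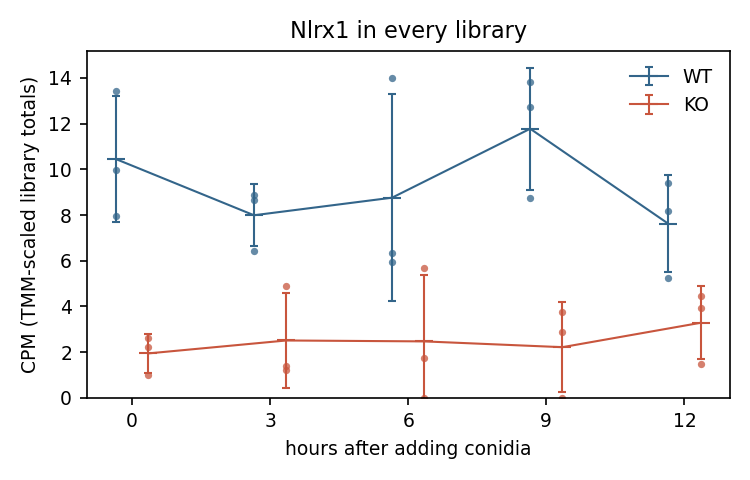
Nlrx1 expression in CPM (vertical axis) by time after challenge in hours (horizontal axis) for WT and KO, with 1 point per library and bars for the mean and SD of 3 libraries. WT libraries lie between 5.26 and 14 CPM and KO libraries between 0 and 5.68 CPM.

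At 3 h in WT cells a small set of early response genes rose. Gem (ENSMUSG00000028214, chromosome 4, 11704457 to 11714752), which encodes a small GTP-binding protein, was among the largest rises, from 0.419 ± 0.727 to 6.49 ± 2.41 CPM, a ratio of the counts pooled over each group of 16.8-fold (counting interval 5.38 to 84.8). Hmox1, the heme-degrading enzyme, rose by 0.71 ± 0.06 and the transcription factor gene Jun by 0.77 ± 0.08. Among migration and maturation genes of dendritic cells the chemokine receptor gene Ccr7 rose by 1.79 ± 0.24, Ccl22 by 0.69 ± 0.10 and Cacnb3 by 1.55 ± 0.25. Ratios given with a counting interval are of pooled, scaled counts and not of mean CPM, and the intervals cover counting error only.

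Of the immediate early genes 7 of 30 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 3.36e-07), led by Jun, Atf3 (0.57 ± 0.07) and Dusp1 (0.81 ± 0.12). In the dendritic cell maturation list 7 of 23 rose (10 adjusted over the list alone, camera adjusted p = 7.88e-10). Among inflammatory cytokines and chemokines 5 of 28 rose (6 adjusted over the list alone, camera adjusted p = 0.00449, adjusted p = 0.124 with an estimated correlation), with Inhba at 0.62 ± 0.09 and Cxcl2 at 0.76 ± 0.11. The heat shock pair Hspa1a (1.35 ± 0.16) and Hspa1b, near-identical copies whose reads may be shared, rose among 14 tested heat shock genes. The stress regulator gene Cebpb rose by 0.40 ± 0.06. The type I interferon list had a higher median (0.51, camera adjusted p = 3.36e-07, adjusted p = 0.297 with an estimated correlation). In the hypoxia list 1 of 22 rose (7 adjusted over the list alone, camera adjusted p = 3.81e-05, adjusted p = 0.055 with an estimated correlation). In all, 126 genes changed, 109 up and 17 down, and 26 of them by at least 2-fold. Without a count filter 58 genes passed, without WT 0 h replicate 3 80, and in a fit of the 6 libraries alone 46, where the calls of Gem (adjusted p = 0.129) and Ccr7 (0.0665) ended.

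At 6 h after challenge WT cells had higher transcripts of cholesterol synthesis and oxidative defence. Hmox1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589) rose from 457 ± 26.9 to 958 ± 52.6 CPM (1.07 ± 0.06, adjusted p = 6.2e-12), and the cystine transporter gene Slc7a11 rose by 0.60 ± 0.04. The iron exporter gene Slc40a1 rose by 2.11 ± 0.17. Gdf15 (ENSMUSG00000038508, chromosome 8, 70629393 to 70632456), a secreted stress-responsive factor of the TGF-beta family, rose by 3.14 ± 0.37, and Gem rose 24.3-fold (counting interval 7.97 to 121). Among the largest falls, Qrsl1 was 23.4-fold (counting interval 6.16 to 199) lower and Trim30c 21.1-fold (counting interval 5.53 to 179.7) lower.

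In the cholesterol synthesis list 10 of 23 rose (17 adjusted over the list alone, camera adjusted p = 4.64e-14), including Insig1 (1.28 ± 0.17). Of the NRF2 list 10 of 24 rose (17 and 2 adjusted over the list alone, camera adjusted p = 5.99e-11), with Txnrd1 at 0.49 ± 0.04. For dendritic cell maturation 8 of 23 rose (9 and 1 adjusted over the list alone, camera adjusted p = 1.32e-07), with Cd83 at 1.93 ± 0.23 and Ccr7 at 1.97 ± 0.24. Of the neutrophil markers 6 of 11 rose (6 adjusted over the list alone, camera adjusted p = 7.8e-07), among them S100a9 (1.13 ± 0.13), Ngp (1.00 ± 0.13) and Chil3 (0.72 ± 0.10). Of the macrophage markers 1 of 14 rose and 4 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.00785, adjusted p = 0.0843 with an estimated correlation), with Csf1r at -0.27 ± 0.05. The pattern recognition gene Ptx3 fell (-0.74 ± 0.09). Glycolysis genes went both ways, 4 of 24 rose and 4 fell (5 and 6 adjusted over the list alone, camera adjusted p = 0.545), with Pfkfb3 up (0.99 ± 0.15) and the glucose transporter gene Slc2a1 down (-0.39 ± 0.06), and their mean (0.11) and median (-0.10) differed in sign. Of 265 structural or small RNA genes 20 rose. In all 408 genes rose and 331 fell, 120 of the 739 by at least 2-fold. With no count filter 367 genes passed, without WT 6 h replicate 2 491 and without WT 6 h replicate 3 469.

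At 9 h oxidative stress and cholesterol genes, and some cytokine genes, were higher in WT cells than before challenge. Hmox1 reached 1169 ± 16 CPM (1.35 ± 0.06), Slc7a11 rose by 0.84 ± 0.04 and Txnrd1 by 0.85 ± 0.04. Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007) rose by 0.94 ± 0.11, from 74.5 ± 2.79 to 143 ± 9.18 CPM, Cxcl2 by 1.29 ± 0.11 and Cxcl3 by 0.89 ± 0.08. Gem rose 46.8-fold (counting interval 15.8 to 229), Spef1 by 3.79 ± 0.87 and Gdf15 by 3.24 ± 0.36. The growth regulator Myc fell (-1.34 ± 0.16), as did the transferrin receptor gene Tfrc (-0.87 ± 0.12).

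Of the NRF2 list 17 of 24 rose (20 and 1 adjusted over the list alone, camera adjusted p = 8.06e-19), and of the cholesterol list 13 of 23 rose (16 adjusted over the list alone, camera adjusted p = 4.85e-13). Inflammatory cytokines and chemokines split, 10 of 28 rose and 5 fell (15 and 6 adjusted over the list alone, camera adjusted p = 0.000154, adjusted p = 0.0562 with an estimated correlation). Among NF-kappaB feedback and subunit genes 13 of 28 rose and 1 fell (15 and 2 adjusted over the list alone, camera adjusted p = 6.96e-07), with Gadd45b at 1.83 ± 0.19 and Traf1 at 1.22 ± 0.18. In the type I interferon list 11 of 43 rose (13 adjusted over the list alone, camera adjusted p = 6.38e-07, adjusted p = 0.298 with an estimated correlation), and its mean log2 CPM was 4.17 in WT 9 h replicate 2 against 3.99 and 3.86 in the others (camera adjusted p at most 1.41e-05 with 1 library left out). The autophagy adaptor Sqstm1 (1.00 ± 0.09) led the list of mitochondrial antiviral genes and Nlrx1 partners, 6 of 22 rose (9 adjusted over the list alone, camera adjusted p = 0.00257). For the unfolded protein and integrated stress response 5 of 26 rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.00963, adjusted p = 0.0784 with an estimated correlation), with Cebpb at 0.75 ± 0.06 and Slc7a5 at -0.97 ± 0.19. Of the macrophage markers 1 of 14 rose and 5 fell (2 and 7 adjusted over the list alone, camera adjusted p = 0.0118, adjusted p = 0.101 with an estimated correlation), with C1qb at -0.66 ± 0.08, and of the 265 structural or small RNA genes 37 fell. The hypoxia list had 3 rises and 4 falls, and its median (0.11) and mean (-0.03) differed in sign. In all 690 genes rose and 596 fell, 240 of them by at least 2-fold. In a fit without a count filter 743 passed, 71.3% of them rises against 53.7% with the filter.

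At 12 h WT cells had raised transcripts of cytokines, chemokines and NF-kappaB targets. Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139) rose from 25.9 ± 3.31 to 184 ± 8.87 CPM (2.82 ± 0.10, adjusted p = 1.37e-17). Tnf rose from 74.5 ± 2.79 to 623 ± 83.5 CPM (3.06 ± 0.11), the activin subunit gene Inhba by 2.95 ± 0.09 and Cxcl2 by 2.92 ± 0.11. Cxcl1 (ENSMUSG00000029380, chromosome 5, 90891241 to 90893115), a neutrophil-attracting chemokine, rose by 5.18 ± 0.25, and Ptgs2 (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227), the inducible cyclooxygenase, by 5.40 ± 0.26. Gem was 207-fold (counting interval 70.6 to 1007) higher than before challenge. Il23a, a subunit of interleukin-23, had no count at 0 h and was at least 13.4-fold higher, and the fatty acid-binding gene Fabp3 at least 14.5-fold, against a floor of 3 counts over the group.

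Of the inflammatory cytokines and chemokines 18 of 28 rose (20 and 1 adjusted over the list alone, camera adjusted p = 1.57e-20). Of the NF-kappaB feedback and subunit genes 23 of 28 rose (24 adjusted over the list alone, camera adjusted p = 5.32e-20), among them the inhibitor Nfkbia (1.39 ± 0.08), Rel (1.48 ± 0.09) and Gadd45b (2.69 ± 0.18). For the immediate early genes 22 of 30 rose and 2 fell (23 and 3 adjusted over the list alone, camera adjusted p = 1.48e-18), with Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984) at 2.42 ± 0.10, Dusp1 at 1.92 ± 0.11 and the nuclear receptor gene Nr4a1 at 5.09 ± 0.55. In the type I interferon list 27 of 43 rose (33 adjusted over the list alone, camera adjusted p = 9.64e-14, adjusted p = 0.11 with an estimated correlation), with Ifit2 at 3.09 ± 0.45 and Ifi204 at 1.52 ± 0.21. In the dendritic cell maturation list 15 of 23 rose and 1 fell (17 and 2 adjusted over the list alone, camera adjusted p = 8.62e-12), with Cd83 at 2.98 ± 0.21, Ccl22 at 1.60 ± 0.10 and the ligand gene Cd274 at 0.60 ± 0.06. Fungal recognition and inflammasome genes split, 13 of 38 rose and 6 fell (14 and 7 adjusted over the list alone, camera adjusted p = 0.0775): Malt1 (0.93 ± 0.08), Cd14 (0.97 ± 0.11) and Tlr2 (0.86 ± 0.11) rose and Clec7a, the beta-glucan receptor Dectin-1, fell (-0.37 ± 0.05).

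Of the hypoxia response genes 9 of 22 rose and 2 fell (11 and 4 adjusted over the list alone, camera adjusted p = 0.00172, adjusted p = 0.114 with an estimated correlation) at 12 h in WT cells. Of the cholesterol list 1 of 23 rose and 1 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.552), with Insig1 at 1.25 ± 0.17. Of the NRF2 list 5 of 24 rose and 3 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.545), and Hmox1 was at 641 ± 60.9 CPM (0.49 ± 0.06). Hspa1a rose by 3.78 ± 0.14 while Hsp90ab1 fell (-0.44 ± 0.05) in a heat shock list with 3 rises and 5 falls, whose median (-0.17) and mean (0.47) differed in sign. Of the mitochondrially encoded transcripts 11 of 13 rose (12 adjusted over the list alone, camera adjusted p = 9.43e-07, adjusted p = 0.239 with an estimated correlation), with mt-Atp8 at 0.74 ± 0.08. At the same time 3 of 265 structural or small RNA genes rose and 48 fell, and small RNA genes (the small nucleolar, small nuclear, Cajal body, micro and miscellaneous RNA biotypes, without rRNA and tRNA) took 3.92% ± 0.092 of the counts (SD, n = 3) against 5.82% ± 0.303 at 0 h. Among macrophage markers 3 of 14 rose and 7 fell (4 and 8 adjusted over the list alone, camera adjusted p = 0.0552), with C1qb (-0.90 ± 0.09) and Apoe (-0.85 ± 0.09) among the falls. In the cell cycle list 4 of 30 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.0658), with Mki67 among the rises (1.08 ± 0.10). The anti-apoptotic Mcl1 rose by 0.72 ± 0.06. Among the largest falls were Pald1 (-2.07 ± 0.27), the DNA-binding inhibitor Id1 (-1.69 ± 0.27), Cdh1, which encodes E-cadherin (-1.64 ± 0.12), and Pwp2 (-1.49 ± 0.30). In all 1195 genes rose and 1050 fell, 556 of them by at least 2-fold. Without a count filter 1486 passed, and 220 with the small RNA share of each library as a covariate, a term added after the data were seen.

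**Figure D2:**
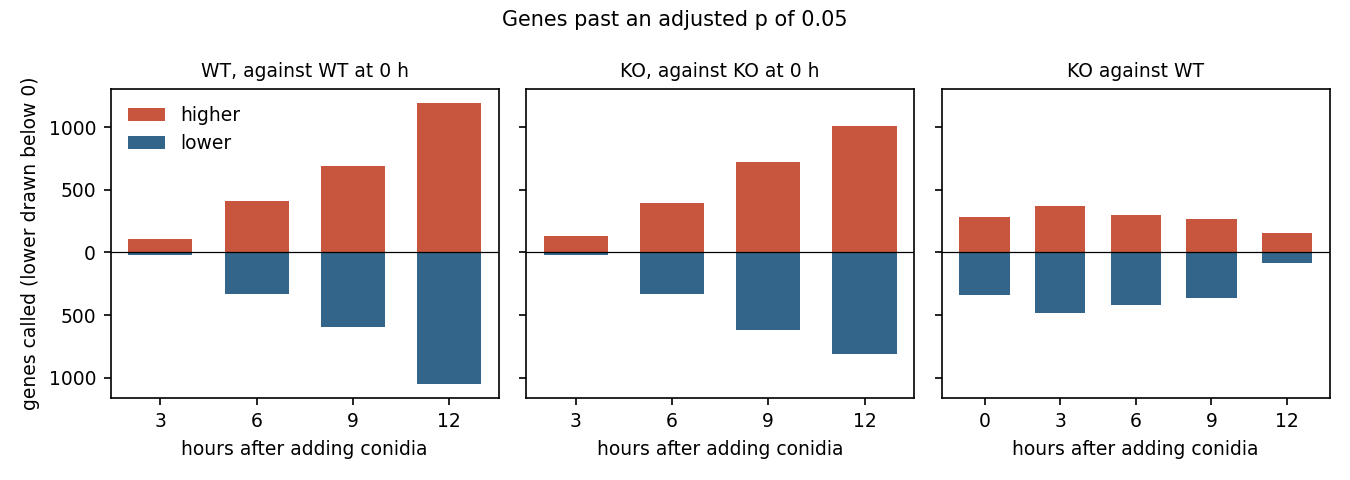
Number of genes past an adjusted p of 0.05 (vertical axis), higher above 0 and lower below 0, for each comparison (horizontal axis), with 12393 genes tested. Calls in the time comparisons grow from 126 (WT) and 151 (KO) at 3 h to 2245 and 1823 at 12 h, and the comparison of genotypes at 12 h has the fewest calls of the 5 times, 236.

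In KO cells several early response and maturation genes rose by 3 h. Gdf15 rose by 3.31 ± 0.49 and Gem by 2.69 ± 0.40. Egln3, a prolyl hydroxylase of the hypoxia pathway, rose by 1.69 ± 0.22. Hmox1 rose by 0.75 ± 0.06 and Jun by 0.68 ± 0.08. Among immediate early genes 7 of 30 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 1.82e-06). In the maturation list 5 of 23 rose (8 adjusted over the list alone, camera adjusted p = 4.61e-05), with Ccr7 at 1.34 ± 0.26. Of the neutrophil markers 2 of 11 rose (2 adjusted over the list alone, camera adjusted p = 0.000354). The type I interferon list had a lower median (-0.30, camera adjusted p = 0.00044, adjusted p = 0.495 with an estimated correlation and 0.0703 without KO 3 h replicate 1). In all 128 genes rose and 23 fell. With no count filter 60 genes passed, and in a fit of the 6 libraries alone 27, where the calls of Gdf15 (adjusted p = 0.0942) and Ccr7 (0.0586) ended.

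At 6 h KO cells showed rises among members of the cholesterol, NRF2 and neutrophil lists. Hmox1 rose from 407 ± 27.6 to 879 ± 59 CPM (1.11 ± 0.06), Gstm1 by 0.80 ± 0.09, Slc40a1 by 1.64 ± 0.17, Gdf15 by 3.88 ± 0.47 and Gem by 3.40 ± 0.37. Pcx, which encodes pyruvate carboxylase, had no count at 0 h and was at least 11.9-fold higher. Of the cholesterol list 9 of 23 rose (14 adjusted over the list alone, camera adjusted p = 7.12e-10). Of the NRF2 list 8 of 24 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 1.8e-06), 6 in all in DESeq2. For neutrophil markers 5 of 11 rose (7 adjusted over the list alone, camera adjusted p = 1.5e-07), with S100a9 at 1.18 ± 0.13 and S100a8 at 1.11 ± 0.14. Cytokine and chemokine genes went both ways, 6 of 28 rose and 7 fell (12 and 8 adjusted over the list alone, camera adjusted p = 0.341), with Cxcl2 up (0.92 ± 0.11) and Ccl4 down (-0.74 ± 0.09). In the maturation list 9 of 23 rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 0.00179). For the unfolded protein and integrated stress response 5 of 26 rose (11 and 1 adjusted over the list alone, camera adjusted p = 0.000216), 3 in all in DESeq2, with Dnajb9 at 0.93 ± 0.16. A nucleotide synthesis gene, Ctps, fell (-2.38 ± 0.45). Of 265 structural or small RNA genes 31 rose and 1 fell. In all 398 genes rose and 335 fell. In a fit without a count filter 456 passed, with 42.3% rises, and with a filter of 1 CPM in 6 libraries 606, with 46.7% rises, against 54.3% in the 733 above, and in a fit of the 6 libraries alone 334.

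At 9 h in KO cells members of the cytokine and immediate early lists rose. Tnf rose from 71.7 ± 7.93 to 227 ± 33.1 CPM (1.67 ± 0.11), Cxcl2 by 1.79 ± 0.11, Inhba by 1.26 ± 0.09 and Egr1 by 1.46 ± 0.11. Nr4a1 rose 39.8-fold (counting interval 10.7 to 333), Gdf15 by 4.70 ± 0.42 and Hmox1 by 1.60 ± 0.06. Pcx was at least 13.4-fold higher. For the cytokine list 12 of 28 rose and 5 fell (12 and 5 adjusted over the list alone, camera adjusted p = 0.000216). Of the immediate early genes 13 of 30 rose and 1 fell (17 and 3 adjusted over the list alone, camera adjusted p = 2.81e-09). In the NF-kappaB list 12 of 28 rose (14 adjusted over the list alone, camera adjusted p = 2.18e-07). Of the NRF2 list 12 of 24 rose (18 and 1 adjusted over the list alone, camera adjusted p = 6.89e-13), and of the cholesterol list 11 of 23 rose (14 and 1 adjusted over the list alone, camera adjusted p = 7.98e-09). Of the iron and metal handling genes 5 of 14 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.00544), with Slc40a1 at 2.05 ± 0.17, the metallothionein gene Mt1 at 0.50 ± 0.07 and Tfrc at -0.71 ± 0.12. Sqstm1 rose by 1.27 ± 0.09. Among neutrophil markers Csf3r fell, and the list's median (-0.09) lay below 0 while the camera direction was up (camera adjusted p = 0.946). In all 726 genes rose and 620 fell. Without a count filter 741 passed and in a fit of the 6 libraries alone 779.

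At 12 h KO cells had high cytokine transcripts. Tnf reached 759 ± 5.68 CPM (3.41 ± 0.11), Cxcl2 rose by 3.13 ± 0.11, Inhba by 2.66 ± 0.09 and Il1b by 2.42 ± 0.09, from 51.7 ± 3.58 to 277 ± 14.9 CPM. Il12b, the shared subunit of interleukins 12 and 23, had no count at 0 h and was at least 45.1-fold higher, Bmp2 at least 15.1-fold and Il23a at least 13.6-fold. Nr4a1 rose 149.7-fold (counting interval 41.1 to 1242), Gem by 6.27 ± 0.28, Ptgs2 by 5.83 ± 0.26 and Gdf15 by 5.13 ± 0.41. Among the largest falls were Lbhd1 (-3.73 ± 0.92), Trub1 (-1.91 ± 0.37), Ttc27 (-1.74 ± 0.44) and Pald1 (-1.62 ± 0.26).

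Of the cytokine list 19 of 28 rose and 1 fell (21 and 1 adjusted over the list alone, camera adjusted p = 4.43e-23), of the NF-kappaB list 23 of 28 rose (25 adjusted over the list alone, camera adjusted p = 9.74e-24), and of the immediate early list 24 of 30 rose and 1 fell (24 and 2 adjusted over the list alone, camera adjusted p = 1.47e-26), where Egr1 rose by 3.04 ± 0.10. In the type I interferon list 31 of 43 rose (35 adjusted over the list alone, camera adjusted p = 1.74e-12, adjusted p = 0.12 with an estimated correlation), with Ifit2 at 2.36 ± 0.39 and Mx1 at 1.28 ± 0.22. For maturation genes 14 of 23 rose and 1 fell (16 and 3 adjusted over the list alone, camera adjusted p = 4.17e-12). In the hypoxia list 12 of 22 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 8.12e-07), with Hilpda at 2.33 ± 0.14 and Egln3 at 2.35 ± 0.22. In the fungal recognition list 12 of 38 rose and 5 fell (13 and 5 adjusted over the list alone, camera adjusted p = 0.141), and its median (-0.02) and mean (0.22) differed in sign. Among mitochondrial antiviral genes and Nlrx1 partners 8 of 22 rose and 1 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.00791), with Sqstm1 at 1.33 ± 0.09 and Optn at 1.85 ± 0.19. Of the nuclear-encoded oxidative phosphorylation genes 6 of 58 fell (6 adjusted over the list alone, camera adjusted p = 0.00333), 2 in DESeq2, with Atp5a1 at -0.30 ± 0.05. Glucose uptake and use gave Slc2a1 (0.46 ± 0.06) and Hk2 (0.44 ± 0.06) as rises, in a glycolysis list where 6 of 24 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.17). Metallothionein genes Mt1 (0.85 ± 0.07) and Mt2 (1.15 ± 0.13) rose. Among macrophage markers 4 of 14 rose and 5 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.705), with Cd68 up (0.51 ± 0.06) and Apoe down (-0.73 ± 0.09). Of 265 structural or small RNA genes 30 rose and 1 fell. In all 1008 genes rose and 815 fell, 410 by at least 2-fold. With no count filter 1187 passed and in a fit of the 6 libraries alone 1162.

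Many genes rose in both genotypes. At 3 h 75 genes rose in both WT and KO against 1.1 given by independent lists, at 6 h 219 against 13.1, at 9 h 425 against 40.4 and at 12 h 624 against 97.2. Falls in both numbered 6, 164, 326 and 431, against 0, 8.9, 29.8 and 69.1. At 9 h 1 gene and at 12 h 2 genes passed in opposite directions. The comparisons share no libraries, since each genotype has its own samples at 0 h.

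**Figure D3:**
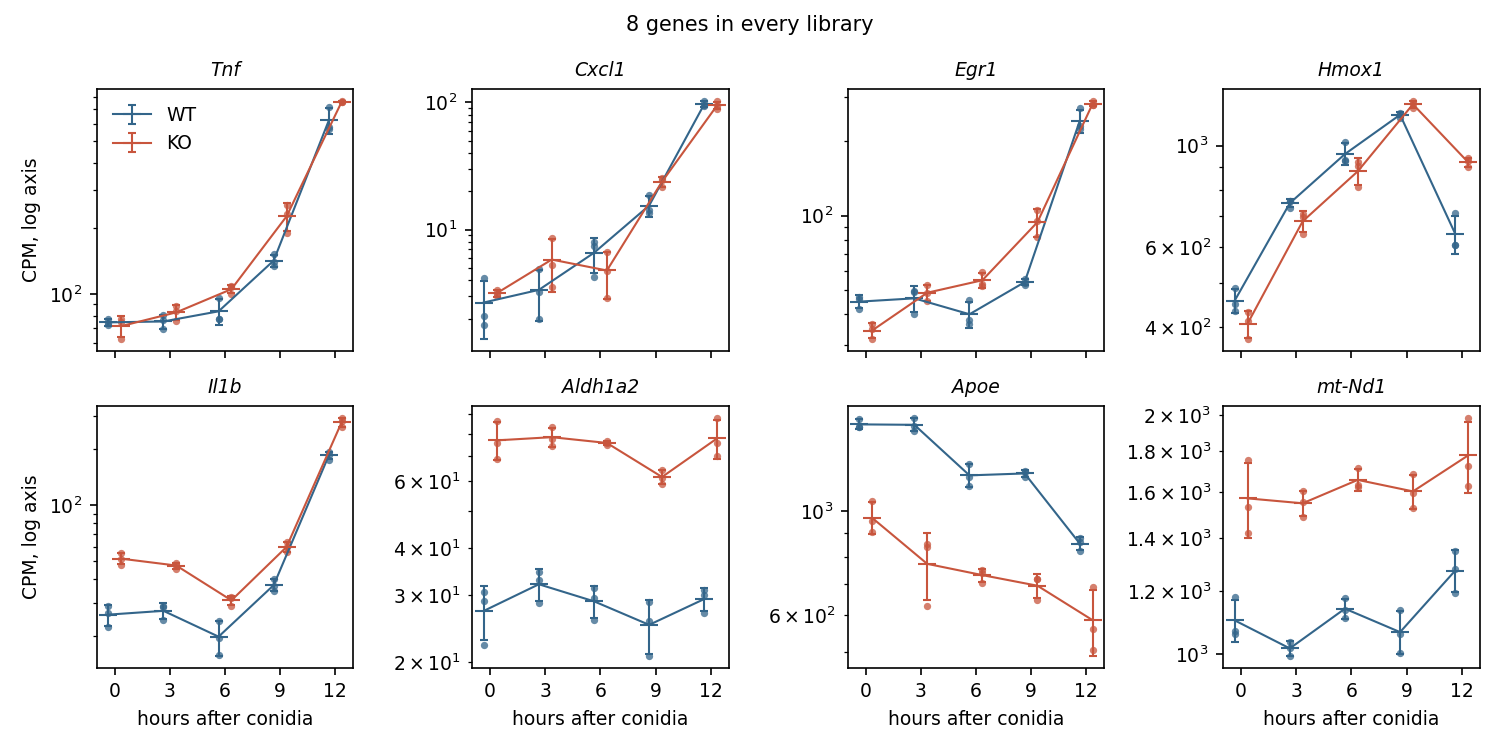
Expression of selected genes in CPM (vertical axis, log scale) by hours after challenge (horizontal axis) in WT and KO cells, with points for single libraries and lines through the means of 3 libraries. Il1b, for example, goes from 25.9 ± 3.31 to 184 ± 8.87 CPM in WT and from 51.7 ± 3.58 to 277 ± 14.9 CPM in KO (mean ± SD).

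Before challenge KO cells already differed from WT cells. Members of the cytokine list were higher in KO, among them Il1b by 0.99 ± 0.11 (51.7 ± 3.58 against 25.9 ± 3.31 CPM), the chemokine gene Ccl22 by 0.98 ± 0.10, Inhba by 0.71 ± 0.09 and Cxcl3 by 0.56 ± 0.08. Aldh1a2 (ENSMUSG00000013584, chromosome 9, 71215789 to 71296243), which makes retinoic acid, was at 76.8 ± 8.82 against 27.3 ± 4.46 CPM, and Syt7 was higher by 1.41 ± 0.24 and Asgr2 by 2.36 ± 0.50. Macrophage-associated transcripts were lower, among them C1qb (-0.80 ± 0.09), Apoe (-0.66 ± 0.09) and Adgre1, which encodes F4/80 (-0.58 ± 0.07). Among the largest falls was Mid1-ps1 (ENSMUSG00000095134, chromosome Y, 90753057 to 90763485), without a count in KO and at least 22.4-fold lower, with its parent gene Mid1 (ENSMUSG00000035299, chromosome X, 169685199 to 170005736) at -2.44 ± 0.29. Reads of this near-identical pair cannot be told apart with certainty.

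All 13 mitochondrially encoded mRNAs were higher in KO at 0 h (13 adjusted over the list alone, camera adjusted p = 3.08e-25, adjusted p = 0.0191 with an estimated correlation), with mt-Atp8 at 1.11 ± 0.08 and mt-Cytb at 0.68 ± 0.07, and their share of the counts was 1.51% ± 0.146 against 0.979% ± 0.064 (SD, n = 3). Among macrophage markers 9 of 14 were lower (11 adjusted over the list alone, camera adjusted p = 5.36e-09). Among neutrophil markers 3 of 11 were lower (5 adjusted over the list alone, camera adjusted p = 0.00033, adjusted p = 0.0671 with an estimated correlation), with Ngp at -0.91 ± 0.14. For cytokines and chemokines 8 of 28 were higher and 1 was lower (8 and 4 adjusted over the list alone, camera adjusted p = 0.0165, adjusted p = 0.223 with an estimated correlation), with a median of -0.01. In the type I interferon list 5 of 43 were higher (13 adjusted over the list alone, camera adjusted p = 5.74e-09, adjusted p = 0.228 with an estimated correlation), 9 in DESeq2, led by Gbp2 (0.83 ± 0.13). Among immediate early genes 1 of 30 was higher and 4 were lower (2 and 6 adjusted over the list alone, camera adjusted p = 0.0338, adjusted p = 0.0904 with an estimated correlation), 2 in all in DESeq2. NRF2 genes Slc7a11 (0.56 ± 0.04) and Nqo1 (0.91 ± 0.19) were higher, as were Cybb, the NADPH oxidase subunit (0.32 ± 0.04), Ptx3 (0.59 ± 0.09) and Cd36 (0.29 ± 0.04), while the cathepsin gene Ctsb was lower (-0.26 ± 0.04). The transcription factor gene Irf4 was higher by 0.49 ± 0.09. Of 265 structural or small RNA genes 5 were higher and 95 lower (median -0.75), and small RNA genes, as defined above, took 3.42% ± 0.077 of the counts in KO and 5.82% ± 0.303 in WT. In all 280 genes were higher in KO and 342 lower. In a fit without a count filter 321 passed, in a fit of the 6 libraries alone 347, and 6 with the small RNA share as a covariate.

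At 3 h members of the cytokine list were higher in KO and members of the macrophage list lower. Inhba was higher in KO by 0.63 ± 0.08, Il1b by 0.80 ± 0.11, Ccl22 by 0.67 ± 0.09 and Cxcl3 by 0.53 ± 0.08. Cbln1 was 12.9-fold (counting interval 4.14 to 64.6) higher and Auts2 higher by 2.49 ± 0.54. Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188) was lower (-0.99 ± 0.09), at 772 ± 124 against 1529 ± 49.2 CPM, and so was C1qb (-0.87 ± 0.09). The metallothionein gene Mt2 was higher (1.05 ± 0.14). Mid1-ps1 was at least 21.9-fold lower and Mid1 was at -2.25 ± 0.29.

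Each of the 13 mitochondrially encoded mRNAs was again higher at 3 h (13 adjusted over the list alone, camera adjusted p = 2.6e-24, adjusted p = 0.0197 with an estimated correlation), with mt-Atp8 (ENSMUSG00000064356, chromosome M, 7766 to 7969) at 1.21 ± 0.08. Of the macrophage markers 1 of 14 was higher and 8 were lower (2 and 11 adjusted over the list alone, camera adjusted p = 1.41e-07), and of the neutrophil markers 3 of 11 were lower (4 adjusted over the list alone, camera adjusted p = 0.0104, adjusted p = 0.155 with an estimated correlation). In the cytokine list 7 of 28 were higher and 3 were lower (8 and 4 adjusted over the list alone, camera adjusted p = 0.132). Of the immediate early genes 1 of 30 was higher and 4 were lower (2 and 10 adjusted over the list alone, camera adjusted p = 0.0218, adjusted p = 0.0671 with an estimated correlation), 3 in all in DESeq2, with Jun at -0.39 ± 0.08. Among lysosomal and oxidase genes 2 of 24 were higher and 6 were lower (6 and 8 adjusted over the list alone, camera adjusted p = 0.217), with Ctsl at -0.64 ± 0.08 and Cybb at 0.29 ± 0.04. For NRF2 genes 4 of 24 were higher (4 and 1 adjusted over the list alone, camera adjusted p = 0.201), with Slc7a11 at 0.46 ± 0.04. The stress genes Atf4 (-0.41 ± 0.07) and Pdia4 (-0.28 ± 0.05) were lower, in a list whose median (-0.06) and mean (0.04) differed in sign. Structural or small RNA genes were lower in 129 cases and higher in 4 of 265 (median -1.08), the vault RNA gene Vaultrc5 (-2.16 ± 0.34) and the mitochondrial tRNA gene mt-Tv (-2.27 ± 0.33) among the largest, and small RNA genes took 3.62% ± 0.076 of the counts in KO against 6.58% ± 0.191 in WT. In all 374 genes were higher and 483 lower. Without a count filter 451 passed (32.2% higher, against 43.6%), in a fit of the 6 libraries alone 456, and 1 with the small RNA share as a covariate.

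At 6 h members of the cytokine list were higher in KO. Cxcl3 was higher by 0.69 ± 0.08, Il1a by 0.83 ± 0.12, Inhba by 0.62 ± 0.08 and Ccl22 by 0.64 ± 0.09. Hspa1a was lower (-0.85 ± 0.13). Sfta3-ps was 39.3-fold (counting interval 6.61 to 1597) higher. Mid1-ps1 was at -3.89 ± 0.55. In the cytokine list 7 of 28 were higher and 3 were lower (11 and 4 adjusted over the list alone, camera adjusted p = 0.00223, adjusted p = 0.125 with an estimated correlation). The 13 mitochondrially encoded mRNAs were all higher (13 adjusted over the list alone, camera adjusted p = 2.6e-24, adjusted p = 0.0197 with an estimated correlation). Among macrophage markers 9 of 14 were lower (10 adjusted over the list alone, camera adjusted p = 9.97e-08), with Apoe at -0.71 ± 0.09 and Gpnmb at -0.25 ± 0.03. Among neutrophil markers 3 of 11 were lower (3 adjusted over the list alone, camera adjusted p = 0.0104, adjusted p = 0.155 with an estimated correlation), with Ngp at -0.78 ± 0.13. Among immediate early genes 2 of 30 were higher and 5 were lower (2 and 6 adjusted over the list alone, camera adjusted p = 0.153), with Atf3 lower (-0.31 ± 0.07). Ptx3 was higher by 0.66 ± 0.09 and Slc7a11 by 0.40 ± 0.04. Of the structural or small RNA genes 3 were higher and 114 lower of 265 (median -0.89), and small RNA genes took 3.87% ± 0.359 of the counts in KO against 6.56% ± 0.239 in WT. In all 300 genes were higher and 416 lower. With no count filter 451 passed (25.7% higher, against 41.9%), in a fit of the 6 libraries alone 382, with protein-coding genes alone 445, without WT 6 h replicate 1 473, and 1 with the small RNA share as a covariate.

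At 9 h members of the cytokine, immediate early and hypoxia lists were higher in KO. Inhba was higher in KO by 1.04 ± 0.08, Il1a by 0.86 ± 0.11, Il1b by 0.68 ± 0.10 and Egr1 by 0.81 ± 0.10, at 94.2 ± 11.8 against 53.9 ± 1.58 CPM. Mt2 was higher by 1.23 ± 0.13 and Mt1 by 0.69 ± 0.07. Ltf, which encodes lactoferrin, was lower (-1.75 ± 0.20), as were Ngp (-1.16 ± 0.14), the iron-binding lipocalin gene Lcn2 (-0.79 ± 0.13) and Mid1 (-2.30 ± 0.26). For cytokines and chemokines 9 of 28 were higher and 1 was lower (10 and 2 adjusted over the list alone, camera adjusted p = 0.000106, adjusted p = 0.0671 with an estimated correlation). Of the immediate early genes 6 of 30 were higher and 1 was lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.0218, adjusted p = 0.0671 with an estimated correlation). For NF-kappaB genes 3 of 28 were higher and 1 was lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.0316, adjusted p = 0.228 with an estimated correlation), with Rel at 0.46 ± 0.08. In the hypoxia list 4 of 22 were higher and 1 was lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.0108, adjusted p = 0.223 with an estimated correlation), with Ero1l at 0.57 ± 0.10. Mitochondrially encoded mRNAs were higher without exception (13 of 13, 13 adjusted over the list alone, camera adjusted p = 3e-35, adjusted p = 0.00473 with an estimated correlation). Among neutrophil markers 5 of 11 were lower (8 adjusted over the list alone, camera adjusted p = 5.12e-09), and among macrophage markers 8 of 14 were lower (10, with 1 higher, adjusted over the list alone, camera adjusted p = 9.58e-07). In the interferon list Gbp2 (0.79 ± 0.12) and Gbp3 were higher, 2 of 43 (3 adjusted over the list alone, camera adjusted p = 0.000185, adjusted p = 0.402 with an estimated correlation and 0.181 without KO 9 h replicate 2). Structural or small RNA genes had 15 higher and 53 lower of 265, and small RNA genes took 3.42% ± 0.302 of the counts in KO against 6.15% ± 0.522 in WT. In all 266 genes were higher and 361 lower. In a fit without a count filter 407 passed (23.3% higher, against 42.4% of the 627), with protein-coding genes alone 439 (50.1% higher), in a fit of the 6 libraries alone 251, without WT 9 h replicate 2 394, without WT 9 h replicate 3 406 and without KO 9 h replicate 2 377. With the small RNA share as a covariate 0 genes passed at 9 h in edgeR's quasi-likelihood test (594 at an unadjusted p under 0.05), while DESeq2 without the covariate called 477.

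At 12 h members of the cytokine and NRF2 lists were higher in KO. Cxcl3 was higher in KO by 0.72 ± 0.08, Il1b by 0.59 ± 0.08, at 277 ± 14.9 against 184 ± 8.87 CPM, Ccl22 by 0.54 ± 0.09 and Ccl17 by 0.40 ± 0.07. Hmox1 was higher by 0.52 ± 0.06, Txnrd1 by 0.36 ± 0.04 and Slc7a11 by 0.33 ± 0.03. Aldh1a2 was higher by 1.39 ± 0.12 and Syt7 by 1.14 ± 0.24. Lower were Ngp (-1.60 ± 0.14), S100a9 (-1.15 ± 0.14), Adgre1 (-0.39 ± 0.06), Mid1 (-2.45 ± 0.27) and Ugt1a7c (-2.14 ± 0.42). For the cytokine list 7 of 28 were higher (10 and 3 adjusted over the list alone, camera adjusted p = 2.7e-06). For NRF2 genes 4 of 24 were higher (8 adjusted over the list alone, camera adjusted p = 2.52e-06). In the antigen presentation list 4 of 19 were higher (9 and 1 adjusted over the list alone, camera adjusted p = 1.45e-05, adjusted p = 0.1 with an estimated correlation). For mitochondrially encoded mRNAs 11 of 13 were higher (13 adjusted over the list alone, camera adjusted p = 5.61e-23), with mt-Co1 at 0.49 ± 0.06. Among neutrophil markers 5 of 11 were lower (7 adjusted over the list alone, camera adjusted p = 2.71e-14), and among macrophage markers 5 of 14 were lower (7, with 1 higher, adjusted over the list alone, camera adjusted p = 3.09e-05). In the type I interferon list 2 of 43 were higher (11 adjusted over the list alone, camera adjusted p = 2.92e-09, adjusted p = 0.225 with an estimated correlation). Its mean log2 CPM in KO replicate 3 (4.46, with 5.54 and 5.11 in the others) lay inside the WT range of 4.31 to 4.85, and the camera adjusted p was at most 0.00476 with 1 library left out. The list of 30 cell cycle genes lay lower (median -0.07, camera adjusted p = 0.0104, adjusted p = 0.0234 with an estimated correlation). Structural or small RNA genes were higher and lower in 4 cases each, and small RNA genes took 3.33% ± 0.177 of the counts in KO against 3.92% ± 0.092 in WT. In all 152 genes were higher and 84 lower. Without a count filter 109 passed (53.2% higher, against 64.4%), in a fit of the 6 libraries alone 84, with the small RNA share as a covariate 64, without WT 12 h replicate 2 143 and without WT 12 h replicate 3 147.

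Averaged over the 5 times, which uses all 30 libraries, the macrophage and neutrophil lists lay lower in KO cells, and members of the cytokine list were higher. Il1b was higher by 0.74 ± 0.05 (adjusted p = 2.58e-12), Inhba by 0.69 ± 0.04, Ccl22 by 0.69 ± 0.04, Cxcl3 by 0.61 ± 0.03 and the guanylate-binding protein gene Gbp2 by 0.75 ± 0.06. Cbln1 was higher by 2.13 ± 0.26. Lower were Apoe (-0.74 ± 0.04), C1qb (-0.67 ± 0.04), Ngp (-1.09 ± 0.06) and Ltf (-1.16 ± 0.09). Among the largest falls was Mid1 (-2.23 ± 0.12).

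Of the mitochondrially encoded mRNAs 13 of 13 were higher (13 adjusted over the list alone, camera adjusted p = 2.77e-26), while the nuclear-encoded oxidative phosphorylation list split, 8 of 58 were higher and 10 were lower (9 and 11 adjusted over the list alone, camera adjusted p = 0.481), 10 in all in DESeq2. In the macrophage list 2 of 14 were higher and 11 were lower (2 and 11 adjusted over the list alone, camera adjusted p = 1.11e-08), and in the neutrophil list 9 of 11 were lower (10 adjusted over the list alone, camera adjusted p = 9.65e-08). Of the cytokine list 14 of 28 were higher and 4 were lower (14 and 4 adjusted over the list alone, camera adjusted p = 0.000764, adjusted p = 0.129 with an estimated correlation). Of the NF-kappaB list 11 of 28 were higher and 2 were lower (11 and 2 adjusted over the list alone, camera adjusted p = 0.0126, adjusted p = 0.207 with an estimated correlation), with Sod2 at 0.33 ± 0.03. In the type I interferon list 15 of 43 were higher (18 adjusted over the list alone, camera adjusted p = 2.14e-05, adjusted p = 0.319 with an estimated correlation). For lysosomal killing and NADPH oxidase genes 6 of 24 were higher and 11 were lower (6 and 13 adjusted over the list alone, camera adjusted p = 0.228), with Cybb higher (0.27 ± 0.02) and Ctsl lower (-0.44 ± 0.03). In the NRF2 list 8 of 24 were higher and 2 were lower (8 and 3 adjusted over the list alone, camera adjusted p = 0.0484, adjusted p = 0.136 with an estimated correlation). For antigen presentation genes 9 of 19 were higher and 2 were lower (9 and 2 adjusted over the list alone, camera adjusted p = 0.0853), with H2-Ab1 at 0.17 ± 0.03. For conventional dendritic cell markers 5 of 11 were higher and 2 were lower (6 and 2 adjusted over the list alone, camera adjusted p = 0.0978), with Irf4 at 0.53 ± 0.04. The 22 mitochondrial antiviral genes and Nlrx1 partners had a median of 0.03 (camera adjusted p = 0.539). Of 265 structural or small RNA genes 11 were higher and 162 lower. In all 1565 genes were higher and 1517 lower, 248 by at least 2-fold, and 4 passed with the small RNA share as a covariate.

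Called at each of the 5 times were 52 genes higher in KO and 29 lower. The higher ones included Il1a (0.65 ± 0.05), Slc7a11 (0.44 ± 0.02), Mt2 (0.83 ± 0.06), Nr4a3 (0.67 ± 0.07) and Ccl17 (0.36 ± 0.03), with values averaged over the times, and the lower ones Gpnmb (-0.24 ± 0.02), Adgre1 (-0.41 ± 0.03), Pdia4 (-0.25 ± 0.02) and S100a9 (-0.77 ± 0.06). On chromosome 9, within 5 Mb of Nlrx1, 19 of 62 tested genes passed on average (30.6% against 24.8% elsewhere, Fisher's exact test, two-sided, p = 0.303), within 10 Mb 35 of 113 (p = 0.154) and within 20 Mb 64 of 218 (p = 0.133).

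**Figure D4:**
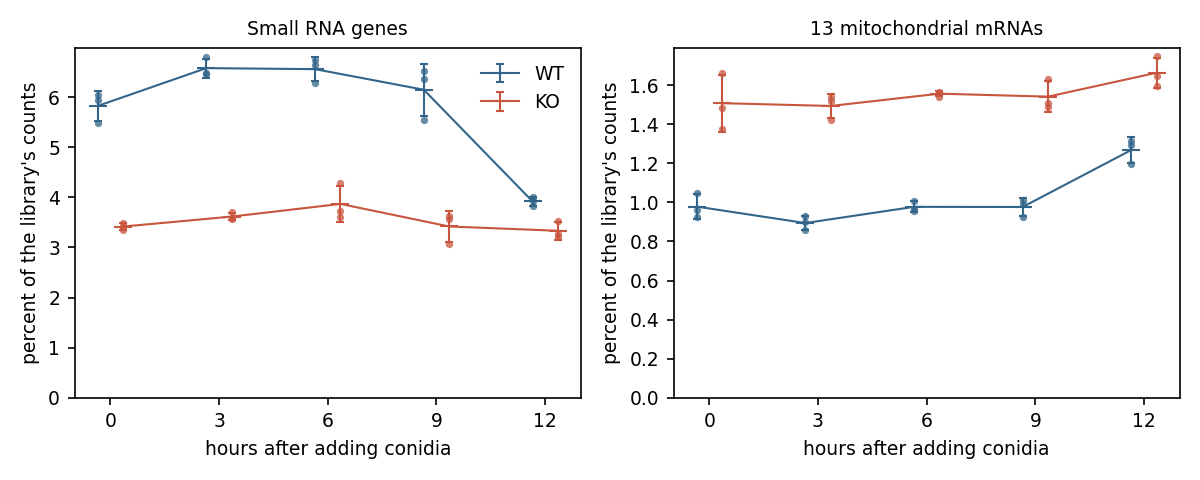
Share of counts in percent (vertical axis) by hours after challenge (horizontal axis) for small RNA genes (without rRNA and tRNA) and for mitochondrially encoded mRNAs, with 1 point per library and the mean of 3 libraries. The small RNA share of WT libraries falls from 6.15% at 9 h to 3.92% at 12 h, inside the KO range of 3.071% to 4.278%, and mitochondrial mRNA is 1.66% in KO and 1.27% in WT at 12 h.

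The interaction of genotype and time tests whether the change from 0 h after challenge differed between genotypes. It gave 110 genes, 51 protein-coding and 59 not. The change of Egr1, at 34.4 CPM in KO and 45 in WT at 0 h, was higher in KO, with a difference of the changes of 1.20 ± 0.15 at 9 h and 0.62 ± 0.14 at 12 h (adjusted p = 0.000355). Hmox1 was higher in KO at 12 h (difference of the changes 0.69 ± 0.09, adjusted p = 5.99e-05), at 919.8 ± 20.5 against 641 ± 60.9 CPM. Mt1 differed by 0.71 ± 0.10 at 9 h (adjusted p = 0.00216), the kinase gene Plk2 by 0.39 ± 0.06 at 9 h and Phlda1 by 0.59 ± 0.14 at 12 h. The mitochondrial mRNA mt-Atp8 differed by -0.69 ± 0.11 at 12 h (adjusted p = 0.000235). Rps7 (adjusted p = 0.00278) and the small nucleolar RNA gene Snord66 (adjusted p = 0.000875) passed over the 4 times together, with -0.46 ± 0.10 at 9 h and 0.99 ± 0.27 at 12 h, values that did not pass at those times alone. Among immediate early genes 1 passed at 9 h (7 adjusted over the list alone, camera adjusted p = 3.09e-06, adjusted p = 0.00212 with an estimated correlation), with a median difference of 0.25. The type I interferon list lay lower in the response of KO at 3 h (median difference -0.81, camera adjusted p = 9.47e-13) and 6 h (-0.47, adjusted p = 0.000449), but not with an estimated correlation (0.363 and 0.704). The list lay higher in KO at 0 h and did not pass between genotypes at 3 h (camera adjusted p = 0.428). Of the glycolysis genes 3 of 24 had a higher change in KO at 12 h (4 adjusted over the list alone, camera adjusted p = 0.00535, adjusted p = 0.11 with an estimated correlation). The small RNA share of the counts was 3.92% ± 0.092 in WT and 3.33% ± 0.177 in KO at 12 h (SD, n = 3). With no count filter 51 genes passed, with protein-coding genes alone 37 and with the small RNA share as a covariate 12. Leaving out WT 3 h replicate 2 gave 71, WT 3 h replicate 3 69, WT 12 h replicate 1 67, WT 12 h replicate 2 62 and KO 12 h replicate 3 65, and without the filter the call of Plk2 ended (adjusted p = 0.17).

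B cell and T or NK cell markers had 1 tested gene each, which did not pass on average, and among erythroid or megakaryocyte markers 1 of 2 was higher (1 adjusted over the list alone), too few for a list test. For mast cell and basophil markers 1 of 3 was lower (1 adjusted over the list alone, camera adjusted p = 0.0853), for eosinophil markers 1 of 5 was higher and 1 was lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.717) with Prg2 at -1.45 ± 0.20, for stromal markers 3 of 7 were higher (3 and 1 adjusted over the list alone, camera adjusted p = 0.16), and for plasmacytoid dendritic cell markers 2 of 5 were higher (3 and 1 adjusted over the list alone, camera adjusted p = 0.19). Of the sex-linked genes 2 of 4 were higher (2 adjusted over the list alone, camera adjusted p = 0.16). Further lists averaged over the times were metal handling, 5 of 14 were higher and 2 were lower (6 and 2 adjusted over the list alone, camera adjusted p = 0.148), cholesterol synthesis, 3 of 23 were higher (3 adjusted over the list alone, camera adjusted p = 0.19), glycolysis, 3 of 24 were higher and 5 were lower (3 and 5 adjusted over the list alone, camera adjusted p = 0.358), hypoxia, 7 of 22 were higher and 3 were lower (9 and 4 adjusted over the list alone, camera adjusted p = 0.142), heat shock, 3 of 14 were higher and 8 were lower (4 and 8 adjusted over the list alone, camera adjusted p = 0.19), unfolded protein response, 3 of 26 were higher and 7 were lower (3 and 8 adjusted over the list alone, camera adjusted p = 0.19), apoptosis, 7 of 25 were higher and 4 were lower (7 and 4 adjusted over the list alone, camera adjusted p = 0.813), fungal recognition, 6 of 38 were higher and 4 were lower (9 and 8 adjusted over the list alone, camera adjusted p = 0.556), dendritic cell maturation, 4 of 23 were higher and 4 were lower (5 and 4 adjusted over the list alone, camera adjusted p = 0.456), and immediate early genes, 4 of 30 were higher and 8 were lower (7 and 10 adjusted over the list alone, camera adjusted p = 0.439). Fungal recognition had a median (-0.01) and a mean (0.04) of opposite sign, and for apoptosis the camera direction was up with a median of -0.04. The cell cycle list had a median of -0.08 (camera adjusted p = 0.481).

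The authors' deposited table of each comparison lists genes at its own threshold. For WT at 3, 6, 9 and 12 h the authors' deposited table lists 33, 160, 370 and 743 genes, of which 28, 144, 344 and 675 passed here in the same direction. In KO cells the authors' deposited table lists 37, 124, 369 and 528, of which 25, 110, 347 and 506 passed here in the same direction. Between genotypes at 0, 3, 6, 9 and 12 h the authors' deposited table lists 157, 193, 154, 144 and 68, with 126, 161, 131, 124 and 48 passing here in the same direction. Nlrx1 is listed in the authors' deposited table at 0 h and 9 h.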

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

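Among the tests below, that of library composition and the list tests of the interaction at single times were chosen after the result was seen.

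The change from 0 h after challenge differed between genotypes for 110 genes in the interaction test (edgeR's quasi-likelihood F test, Benjamini-Hochberg adjusted). In 100 shuffles of the genotype labels within each time, the real one included, 3 gave as many calls and the highest other count was 130, a share under 0.05, though shuffling also breaks up the standing difference between genotypes. Genes switching within a group (0.9% of the 110) are argued against as the whole cause. Library make-up from small RNA stays open: fitting protein-coding genes alone (70.6% of the 51 passed) changed scaling little. With the small RNA share as a covariate 11 of the 110 passed. Library preparation between WT 9 h and WT 12 h stays open for the 51 and the 59 other genes. It would leave no difference at 9 h. Median differences of the 59 were 0.793 at 9 h and 0.995 at 12 h. Some genes lay near 0 at 9 h, such as Gm24270 (0.06 and 0.995) and protein-coding Rps26 (0.01 and -0.48), but not Egr1 (1.20 and 0.62). A response that depends on Nlrx1 may underlie some of the 51, as a hypothesis found and tested on the same data.

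Hmox1 rose more in KO than in WT by 12 h, with a difference of the changes of 0.688 (adjusted p of the interaction 5.99e-05). At 9 h the change from 0 h was higher in KO than in WT for Egr1, by 1.197 (adjusted p = 0.000355), the metallothionein gene Mt1, by 0.711 (adjusted p = 0.00216) and the kinase gene Plk2, by 0.394 (adjusted p = 0.00212). Phlda1 differed by 0.587 at 12 h (adjusted p = 0.00221), and the small nucleolar RNA gene Snord66 by 0.994 at 12 h (adjusted p = 0.000875). The difference for mt-Atp8 was -0.689 at 12 h (adjusted p = 0.000235), and for the ribosomal protein gene Rps7 it was -0.459 at 9 h (adjusted p = 0.00278). Snord66 and Rps7 passed over the 4 times together but not at the time given alone. The immediate early list differed at 9 h with a camera adjusted p of 3.09e-06 (adjusted p = 0.00212 with an estimated correlation). Of 112 list tests at single times 13 passed, 1 of them with an estimated correlation too.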

How the results depend on the processing

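Protein-coding genes alone and the small RNA share as a covariate were chosen after the data were seen. No call of a named gene reversed in the first group of alternatives, the only ones so checked. DESeq2, RLE factors, the 1 CPM filter and removal of switching genes left each call count within 1.5 times. Without a count filter, where 46958 genes share the adjustment, the counts fell at 3, 6, 9 and 12 h to 58, 367, 743 and 1486 in WT and 60, 456, 741 and 1187 in KO, between genotypes at 0 to 12 h to 321, 451, 451, 407 and 109, and for the interaction to 51. In fits of the 6 libraries of a comparison alone, which have fewer residual degrees of freedom, the counts were 46 for WT at 3 h, 27, 334, 779 and 1162 in KO, and 347, 456, 382, 251 and 84 between genotypes. With protein-coding genes alone, fewer genes were tested, and 445 passed between genotypes at 6 h and 37 for the interaction. With the small RNA share as a covariate 220 passed for WT at 12 h, 12 for the interaction, 4 on average, and 6, 1, 1, 0 and 64 between genotypes (0 at 9 h in edgeR, with 594 at an unadjusted p under 0.05 and 477 in DESeq2 without the covariate). The share itself differs between genotypes at 0 to 9 h, so the covariate removes much of the contrast by construction.

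With 1 library left out the counts ran from 80 to 106, 469 to 566, 906 to 1100 and 1663 to 1879 in WT, and from 103 to 115, 490 to 649, 977 to 1131 and 1360 to 1607 in KO. Between genotypes they ran from 434 to 499, 578 to 692, 473 to 569, 377 to 549 and 143 to 193, for the interaction from 62 to 126 and on average from 2886 to 3025. They moved by over 1.5 times without WT 0 h replicate 3 (WT 3 h, 80), WT 6 h replicate 2 (WT 6 h, 491) or 3 (469), WT 6 h replicate 1 (KO against WT, 473), WT 9 h replicate 2 (394) or 3 (406), KO 9 h replicate 2 (377), WT 12 h replicate 2 (143) or 3 (147), and for the interaction without WT 3 h replicate 2 (71) or 3 (69), WT 12 h replicate 1 (67) or 2 (62), or KO 12 h replicate 3 (65). Fewer libraries lower the power, and beyond that the cause was not tested.

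The share of higher genes among the calls depended on the count filter. Without a filter it was 71.3% for WT at 9 h (53.7% with it), 42.3% for KO at 6 h (54.3%), 32.2%, 25.7%, 23.3% and 53.2% between genotypes at 3, 6, 9 and 12 h (43.6%, 41.9%, 42.4% and 64.4%) and 44.1% on average (50.8%). With the filter of 1 CPM it was 48.0% for WT at 12 h (53.2% above), 46.7% for KO at 6 h, 31.0% and 30.3% between genotypes at 0 and 6 h (45.0% and 41.9% above) and 49.2% on average. With protein-coding genes alone it was 50.1% between genotypes at 9 h, and without switching genes 48.5% on average. With the small RNA share as a covariate it was 72.3% for WT at 12 h. With 1 library left out the share on average fell below 50% in many cases, to 47.7% at the lowest, so no majority direction is given for it.

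Calls of named genes were lost in 62 of 1078 cases in DESeq2, 250 of 1127 without a filter, 272 of 1004 in fits of 6 libraries, 127 of 1127 with the filter of 1 CPM and 978 of 9714 with 1 library left out. Of 134 called list tests (504 run) 69 lost their call with an estimated correlation, and 44 did so with 1 library left out in at least 1 case. At 9 h between genotypes the interferon (adjusted p = 0.181) and NF-kappaB (0.2) lists did so without KO 9 h replicate 2.

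The replicate numbers did not pair the samples: libraries with the same number had mean correlations of their deviations of 9e-04, 0.0088 and 0.0012 (lowest -0.0736), and 11 of 30 correlated best with their own number. With the replicate block the counts were 128, 725, 1276 and 2231 in WT, 147, 717, 1330 and 1815 in KO, 615, 856, 699, 590 and 217 between genotypes, 90 for the interaction and 3060 on average. Under the block 4 list tests lost their call (NRF2 on average, adjusted p = 0.0557, and at 12 h heat shock 0.0584, conventional dendritic cell 0.0523 and mast cell 0.0506) and 1 gained it (Nlrx1 partners in KO at 6 h, 0.0481).

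For comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05, and only the real one gave as many genes. The real counts were 126, 739, 1286 and 2245 in WT against at most 2 genes in other splits, 151, 733, 1346 and 1823 in KO against at most 2, and 622, 857, 716, 627 and 236 between genotypes against at most 3. For the average over times 1 of 100 shuffles, the real one, gave as many as 3082 genes, with 743 the highest other. That argues against a chance division of libraries but not of cultures. Counts of Nlrx1 of 0 to 46 per library and totals of at most 3509429 limit what could be detected for genes of low expression.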

Other observations

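The tests of explanations in this part, apart from that of short inserts, were chosen after the result was seen, as were some of the genes named. The chaperone gene Hspa1a rose at 12 h in KO (3.52 ± 0.14), while the mitochondrial chaperonin gene Hspd1 fell at 9 h in WT (-0.51 ± 0.07) and KO (-0.56 ± 0.07) and Hsph1 fell at 12 h in WT (-0.34 ± 0.07) and KO (-0.54 ± 0.07). Pmaip1, which encodes the pro-apoptotic protein NOXA, rose at 12 h by 1.67 ± 0.17 in WT and 1.06 ± 0.16 in KO, as did the anti-apoptotic Mcl1 in KO (0.74 ± 0.06). Ppp1r15a, a phosphatase subunit of the integrated stress response, rose by 2.27 ± 0.46 in WT and 2.59 ± 0.48 in KO. In WT at 12 h the serine synthesis gene Psat1 (-1.31 ± 0.19) and the amino acid transporter gene Slc7a5 (-1.02 ± 0.19) fell.

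Between genotypes, averaged over the times, the transcription factor gene Runx2 was higher in KO by 0.38 ± 0.09 and the chemokine receptor gene Ccr9 by 0.79 ± 0.22, while the stem cell factor receptor gene Kit (-0.59 ± 0.14), Gata2 (-0.55 ± 0.10) and Irf8 (-0.25 ± 0.05) were lower. Class I antigen presentation genes B2m (0.24 ± 0.05) and Nlrc5 (0.34 ± 0.08) were higher, and class II loading genes H2-DMa (-0.18 ± 0.05) and H2-DMb1 (-0.17 ± 0.04) lower. Vcam1 was higher by 0.84 ± 0.21 and the eosinophil-associated ribonuclease gene Ear2 by 0.90 ± 0.18. Trp53, which encodes p53, was lower (-0.29 ± 0.07). Nnt (ENSMUSG00000025453, chromosome 13, 119335448 to 119408997 in GRCm38), a mitochondrial transhydrogenase gene that differs between C57BL/6 substrains, was higher in KO by 0.65 ± 0.13 (adjusted p = 0.000427). Of the Y-linked genes Ddx3y was higher by 0.15 ± 0.05 and Eif2s3y by 0.24 ± 0.08, calls that ended without a count filter (adjusted p = 0.276 and 0.156) and with the filter of 1 CPM (0.083 and 0.0685). Of the 10 tested genes nearest to Nlrx1, H2afx (-0.32 ± 0.08) and Nectin1 passed on average and 8 did not. Nectin1 had no count in KO at 0 h, did not pass between genotypes from 3 h on, and passed for the interaction (adjusted p = 0.0229). Mitochondrial rRNA took 7.22% ± 0.359 of the counts at 0 h in WT and 10.004% ± 0.52 in KO (SD, n = 3), and 9.602% ± 0.418 and 10.86% ± 0.391 at 12 h.

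Small RNA (235 tested genes) was lower in KO and mitochondrial mRNA higher, with medians over the genes of -0.62 and 0.64 on average over the times. More mitochondria per cell are argued against by nuclear-encoded oxidative phosphorylation genes, whose median was -0.028 (SD over genes 0.157). Protein-coding genes alone (mitochondrial mRNA median 0.627) scaled alike, so library composition stays open. For mitochondrial mRNA a library batch setting WT 0 to 9 h apart is argued against only as the whole cause. At 12 h 11 of 13 were higher in KO, though WT rose from 0.976% of counts at 9 h to 1.268%. For small RNA the batch cannot be told apart from genotype. All 3 WT 12 h libraries lay in the KO range of 3.071% to 4.278%, against 6.15% at 9 h. Short inserts lost from the KO libraries cannot be told apart either. The 1051 shortest protein-coding genes lay -0.117 from the others at 3 h (-0.089 against 0.028), a small part of the small RNA median (-1.08). An effect of Nlrx1 loss on mitochondrial mRNA stays open, untested, as do differences between animals or cultures.

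The macrophage and neutrophil marker lists lay lower in KO at each time by camera, the neutrophil list at 0, 3 and 6 h only with the preset correlation. A fit of protein-coding genes alone (macrophage median -0.296, -0.289 with all genes) changed the scaling little, so it does not decide on library composition. Below 0 on average lay 12 of 14 macrophage and all 11 neutrophil markers (median -0.765). A smaller share of macrophage-like and neutrophil-like cells in the KO cultures is a candidate explanation that these markers cannot test. Lower marker expression within each cell cannot be told apart from it in RNA of whole cultures, as dendritic cells express several of these markers too. In edgeR 0 of 25 had an interaction (13 at an unadjusted p under 0.05, and 0 in DESeq2). By camera the neutrophil list did at 9 h (adjusted p = 0.0424) and 12 h (0.0237) and the macrophage list at 12 h (0.0351). None held with an estimated correlation or each library left out.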
